A study of Arabidopsis thaliana with 3 samples.

How the data were processed

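Leaf RNA from 2 week old Arabidopsis thaliana plants was measured on 3 arrays, 1 for each genotype: untreated Col-0, the common laboratory accession, and a pair of MKK2 lines in the Col-0 background. The study's subject was the overexpression of MKK2, a MAP kinase kinase, as the wild-type protein and as a constitutively active variant. The labels contradict each other on which array holds which variant. The array called line A here has w.t.4 in its title and EE4 in its source name, and the array called line B has EE4 in its title and w.t.4 in its source name. Neither label was preferred, so no direction between the wild-type and the active variant is given. Each genotype has 1 array, so no test across samples could be made and no value has a replicate error.

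The authors deposited 1 intensity per probe set and array on a linear scale. It is a MAS5 signal, per the submitters' processing notes, which combines the perfect-match and mismatch probes of a probe set into 1 value. The software version, scanner settings and detection calls are not given in the sources used here. The mean signal after trimming 2% of the probe sets at each end was 100.01 on every array, as after scaling to a common target of 100. All deposited intensities were above 0. Such scaling assumes that the bulk of the signal is the same in every sample.

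Each array was scaled again to a trimmed mean of exactly 100, which changed almost nothing. Signals under a floor of 25 were set to 25 before log2 ratios were taken, because MAS5 signals near background are imprecise and no detection calls were used. A ratio against a signal under the floor is therefore a lower bound. Of 22810 probe sets, 64 Affymetrix controls were left out of the comparisons, which leaves 22746. A probe set was counted as higher or lower at a ratio of 2-fold or more. No depth exists for arrays. Their number limits the precision.

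Gene names came from the platform annotation, updated through the gene numbers of the TAIR10.1 reference. It gave 1 gene for 13513 of the compared probe sets, several for 503 and none for 8730. Of the first group, 13436 matched a reference locus, and 11933 carry only a locus tag in place of a symbol. Many well-studied genes are among the unnamed probe sets. Names and gene lists thus cover part of the array, while counts cover all of it. The chip's genome build is not given in the sources used here, so no coordinates are printed. Probe sets whose name ends in _s_at or _x_at, 1061 in all, can read more than 1 gene.

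The following choices were made before the data were examined. Named genes are the 10 highest and 10 lowest of each line against Col-0, the 6 furthest each way in both lines (ranked by the smaller of the ratios), and the 6 furthest each way between the lines. The higher of the signals had to be at least 100 and the probe set had to name 1 gene. From each list, the members furthest from 0 were added. The 21 lists hold 308 genes, of which 33 have a named probe set, and the 7 lists with 3 or more such genes were evaluated. The lists left out for that reason are the MAP kinase cascade, salt, drought and abscisic acid, jasmonate, ethylene, heat shock, oxidative stress, circadian clock, senescence, glucosinolate, cell division, and the root, flower, seed and guard cell markers. A gene with several probe sets was represented by the brightest. Each list's median log2 ratio was set against 10000 random lists of the same size, drawn for each member from the 200 probe sets nearest in mean signal. This describes these arrays and is not a test across plants.

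Both lines were compared with the same Col-0 array, so chance deviations of that array enter both ratios. Unchanged arrays were simulated 100 times. The noise of each simulated array was taken from the difference between lines A and B at probe sets of similar signal, divided by the square root of the number of arrays in that difference. This noise includes any real difference between the lines. Each difference was given a random sign, and the floor was applied to the simulated arrays afterwards. The counting was tested on simulated data in which 200 of 22746 probe sets were changed in line A against Col-0. All 200 had a mean signal of at least 100, so recovery at dimmer probe sets was not tested. The counting called 66% of the 50 changed 2-fold, 100% of the 50 changed 3-fold and 100% of the 100 changed 4-fold. Of the unchanged ones, bright and dim, it called 0.918%.

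Alternatives were no rescaling, quantile normalization, loess centring (span 0.4), floors of 10 and 50, a pseudocount of 16 without a floor, thresholds of 1.5-fold and 3-fold, and leaving out probe sets with a suffix such as _s_at or _x_at. The variant names of the lines were also exchanged, as the source names would have them. For the lists they were the mean of a gene's probe sets and the mean in place of the median. Gene families and plastid genes were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.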

Results

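Gene expression was profiled in leaves of 2 week old plants on 3 arrays: Col-0, MKK2 line A (titled w.t.4, source name EE4) and MKK2 line B (titled EE4, source name w.t.4). Median signals were 35.3 in Col-0, 31.5 in line A and 34.2 in line B. Signals reached the floor of 25 at 13197 probe sets in Col-0, 12396 in line A and 13034 in line B. Log2 signals correlated across probe sets with r = 0.978 between line A and Col-0, 0.981 between line B and Col-0, and 0.987 between the lines. Where both signals were at least 100, the central 95% of probe sets lay between 0.669-fold and 1.90-fold for line A over Col-0, between 0.649-fold and 1.69-fold for line B over Col-0, and between 0.711-fold and 1.52-fold for line A over line B. No genotype was replicated, so these ranges hold both array noise and real differences. The 3′ to 5′ signal ratio of the actin control, a sign of RNA integrity, was 3.03 in Col-0, 4.09 in line A and 3.83 in line B. That of the GAPDH control was 2.19, 2.29 and 2.39, and that of the ubiquitin control 3.75, 2.92 and 3.02. A second set of control probe sets gave 2.83, 2.88 and 3.08 for actin and 0.816, 1.15 and 0.966 for GAPDH. For ubiquitin it gave 2.03, 1.77 and 1.80. The rise for actin was thus much smaller in the second set. Of all 6 control ratios, 4 were above Col-0 in both lines and 2, both of ubiquitin, below it.

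The first question is whether MKK2 transcript was raised in the lines. No probe set is named as MKK2 in the annotation used here, so its signal is not reported, and the overexpression was not checked on these arrays. The same holds for the other 17 members of the MAP kinase cascade list, among them MPK4 and MPK6, the kinases known to act below MKK2.

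Line A was compared with Col-0 to find the genes that differ in the first MKK2 line. Ranked with signals under 25 set to 25, EXO, AT1G33760 and CML38 led the named genes above Col-0. EXO, a brassinosteroid-responsive gene of cell expansion, had a signal of 1602 in line A against 117 in Col-0, a 13.6-fold difference. CML38, a calmodulin-like calcium sensor, was 9.54-fold higher (267 against 28.0). AT3G04640, which encodes a glycine-rich protein, was 8.33-fold higher, and AT2G27080, of the NDR1/HIN1-like family, was 7.59-fold higher. AT1G33760, an AP2/ERF transcription factor gene, was at least 10.1-fold higher, with a Col-0 signal of 2.99 under the floor. AT5G52050, the efflux carrier gene DTX50, was at least 7.12-fold higher. AT5G05600, an enzyme gene of jasmonate hydroxylation, was 6.63-fold higher. PUB23, a U-box ubiquitin ligase that restrains pattern-triggered immunity, was 6.49-fold higher. AT4G29780 and AT2G41640, a glycosyltransferase gene, were 6.46-fold and 6.09-fold higher.

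Differences below Col-0 were smaller in line A. AT1G04770, a gene related to the sulphur deficiency-induced SDI1, was 3.72-fold lower (103 against 384). AT1G47970, AT3G45210 and AT4G01810 were 3.13-fold, 3.05-fold and 3.05-fold lower. AT3G50430 was 2.69-fold lower and AT1G72410 was 2.63-fold lower. AT1G49200 was 2.36-fold lower, and AT1G64380, another AP2/ERF gene, was 2.28-fold lower. PORB, a light-dependent enzyme of chlorophyll synthesis, was 2.26-fold lower (192 against 435), and DIM1A, an rRNA dimethyltransferase, was 2.24-fold lower. In all, 318 of 22746 probe sets were 2-fold or more higher in line A and 89 were lower. In unchanged simulated arrays 102 probe sets were higher (range 68 to 126) and 102 lower (80 to 117). The observed number of higher probe sets lay above the simulated range and that of lower ones within it. For the lower ones this decides nothing, for a reason given below with the shared counts. With a floor of 10 in place of 25, 508 probe sets were lower and 46.9% of the differing probe sets were higher, against 78.1% at the floor of 25. At a threshold of 1.5-fold, 754 were higher and 891 lower, so the majority changed sides.

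Line B was compared with the same Col-0 array. EXO, PDF1.2 and PDF1.2b stood furthest above it among named genes. EXO was 10.5-fold higher (1227 against 117), CML38 6.08-fold, AT5G05600 5.51-fold and AT3G04640 4.41-fold. PDF1.2, a defensin commonly used as a marker of jasmonate and ethylene signalling, had a signal of 519 against 70.1, a 7.40-fold difference. The probe set of PDF1.2b, which can read other defensin genes too, had a signal of 975 against 139. Both were also above Col-0 in line A, PDF1.2 3.93-fold and PDF1.2b 3.96-fold. EXLA1, an expansin-like cell wall gene, was 4.65-fold higher. AT2G20670 was 4.77-fold higher, AT1G72920, a Toll/interleukin receptor domain gene, 4.38-fold, and AT1G61890 4.36-fold. In line A these genes were 3.48-fold, 4.02-fold and 3.48-fold higher.

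The named genes furthest below Col-0 in line B were AT5G03350 and AT3G22240. AT5G03350, which encodes a lectin-like protein induced by salicylic acid, was 3.58-fold lower (142 against 510). AT3G22240 was 3.34-fold lower (1342 against 4485) and AT1G19960 was 2.99-fold lower. AT1G04770 and AT1G47970 were 2.78-fold and 2.70-fold lower. AT4G34950, AT1G28260 and AT3G47800 were 2.40-fold, 2.32-fold and 2.25-fold lower. AT1G23840 had a signal of 57.8 against 145. AT1G10340, an ankyrin repeat gene, was 2.24-fold lower in line B. In all, 214 probe sets were 2-fold or more higher in line B and 122 were lower. The simulated unchanged arrays gave 102 higher (range 73 to 126) and 101 lower (79 to 119), so both observed numbers lay above the simulated ranges. Here too the simulation is not a safe measure of lower probe sets. With a floor of 10, 405 probe sets were higher and 360 lower, so 52.9% of the differing probe sets were higher, against 63.7% at the floor of 25. At 1.5-fold, 701 were higher and 709 lower.

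The changes that both lines share do not depend on which line carries which variant. EXO, CML38, AT5G05600, EXLA1, AT3G04640 and AT2G27080 were furthest above Col-0 in both. EXLA1 was 4.95-fold higher in line A and 4.65-fold in line B, and AT2G27080 was 7.59-fold and 4.26-fold higher. AT1G04770, AT1G47970, AT3G45210, AT4G34950, AT3G47800 and AT3G44450 were furthest below Col-0 in both. AT3G45210 was 3.05-fold lower in line A and 2.21-fold in line B. AT3G44450, known as the cryptochrome inhibitor BIC2, was 1.83-fold and 2.11-fold lower, and AT4G34950 was 1.87-fold and 2.40-fold lower. With signals under 25 set to 25, the highest ratio in both lines belonged to a probe set whose gene is not named here, with signals of 60.9 in Col-0, 975 in line A and 713 in line B.

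**Figure D1:**
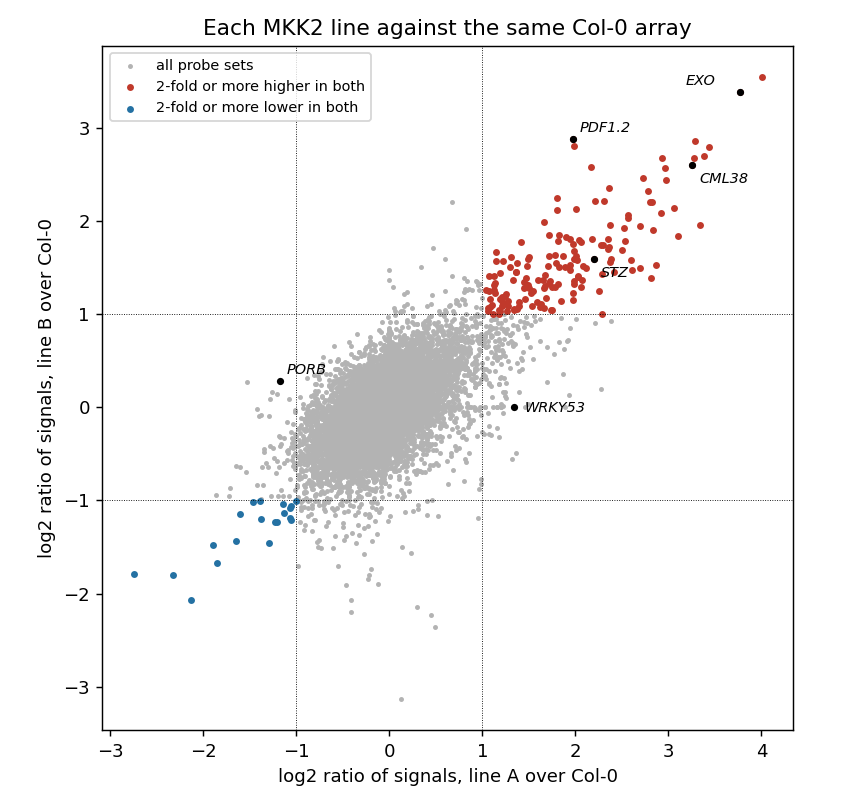
Log2 ratio of scaled signals over Col-0 for each probe set, with line A on the horizontal and line B on the vertical axis. Dotted lines mark 2-fold, red points are the 159 probe sets higher in both lines, blue points the 20 lower in both, and black points are genes named in the text.

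**Figure D2:**
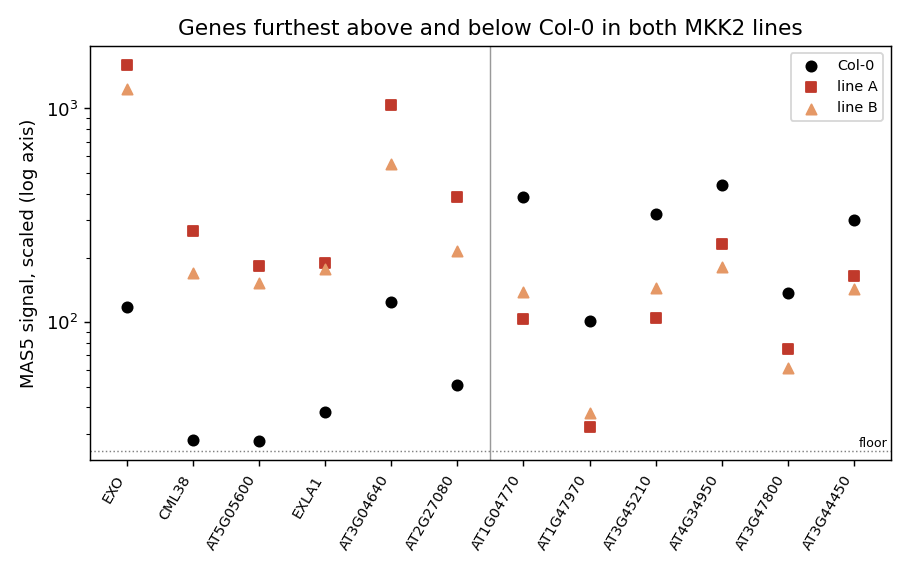
Scaled MAS5 signal on a log axis in each of the 3 arrays for the 6 named genes furthest above and the 6 furthest below Col-0 in both lines. Each marker is 1 array without replicate error, and EXO spans the widest range, from 117 in Col-0 to 1602 in line A.

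Both lines shared 159 probe sets that were 2-fold or more higher and 20 that were lower, and none was 2-fold higher in one line and 2-fold lower in the other. Independent lists of these sizes would share 2.99 higher and 0.477 lower probe sets. Simulated unchanged arrays that shared 1 Col-0 array gave 12.6 higher in both (range 2 to 22) and 50.2 lower (31 to 66). At the floor of 25, which the simulation also used, the shared higher number thus lay above the simulated range. The shared lower number lay below it, and the simulated unchanged arrays held more shared falls than rises. Random signs can lift dim Col-0 signals over the floor, so the simulation is not a safe measure of lower probe sets. A floor of 10 gave 221 probe sets higher and 110 lower in both, so 66.8% were higher, against 88.8% at the floor of 25, and the 1.5-fold threshold gave 411 higher and 264 lower. The ratios of the lines correlated across probe sets with r = 0.668, against 0.501 in the simulation, and their covariance was 0.069 against 0.040. The simulation gives every array equal noise, taken from the lines, so its r of 0.501 follows from that setting. More noise on the Col-0 array alone would also raise r and the covariance. Part or all of their excess may thus come from the single shared Col-0 array, which could not be split. Genes are not independent replicates, and all shared values rest on that 1 array.

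Line A was set against line B to compare the MKK2 variants. The source names turn the direction between variants that the titles give, so only the lines are compared. AT1G24140 and AT2G18690 stood furthest above line B among named genes. AT1G24140, a matrix metalloproteinase gene, was 4.23-fold higher in line A (289 against 68.4). AT2G18690 was 3.59-fold, AT1G10340 3.24-fold, AT5G03350 3.05-fold and AT3G22240 2.91-fold higher in line A than in line B. AT1G33760 was 2.59-fold higher. For AT5G03350 and AT3G22240 line A lay near Col-0, at 0.851-fold and 0.872-fold of it, and line B lay below.

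PORB was 2.76-fold higher in line B than in line A (529 against 192), with Col-0 at 435. AT3G50430 and AT1G72410 were 2.64-fold and 2.47-fold higher in line B than in line A, and Col-0 was 1.02-fold and 1.06-fold above line B. AT5G02830, AT5G48490, a lipid transfer protein gene, and AT2G40430 were 2.08-fold, 2.06-fold and 2.05-fold higher in line B. In all, 133 probe sets were 2-fold or more higher in line A than in line B and 41 were lower. With a floor of 10 the numbers were 276 and 346, and at 1.5-fold they were 533 and 550, so the majority changed sides in each. No spread independent of these arrays exists against which to set the counts.

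Gene lists fixed beforehand were thinly covered. Of 5 cold response genes with a named probe set, 2 were 2-fold or more higher in line A and 1 in line B. STZ (ZAT10), a zinc finger repressor gene that also responds to many other stresses, was 4.59-fold higher in line A (2751 against 599) and 3.01-fold in line B. COR47, a dehydrin, was 2.03-fold and 1.61-fold higher. COR15A, a chloroplast cold-protection gene, had log2 ratios of -0.24 and -0.27, and COR15B of -0.21 and 0.46. The list's median log2 ratio was 0.18 in line A and 0.46 in line B, while 95% of random lists lay between -0.37 and 0.16 and between -0.33 and 0.28. The line A median was the value of LTI30, another dehydrin, whose Col-0 signal of 14.3 was under the floor. It was 0.98 with a floor of 10 and 0.00 with a floor of 50.

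Touch and wounding genes numbered 4, and 2 of them were 2-fold or more higher in line A and 1 in line B. CML38 led in both. CML37, a related calcium sensor, was at least 2.04-fold higher in line A and under the floor in Col-0 and line B. ORA47, an AP2/ERF regulator of jasmonate synthesis, had a signal of 150.2 in Col-0, 150.1 in line A and 249 in line B. CML39 (AT1G76640) was under the floor on all arrays. The list's median log2 ratio was 0.51 in line A (random lists -0.30 to 0.17) and 0.37 in line B (-0.31 to 0.24), and 0.32 between the lines (-0.24 to 0.17). The line A median was 0.95 with a floor of 10 and 0.01 with a floor of 50, where the median between the lines was also 0.01.

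Of 3 genes of pattern-triggered defence, WRKY22, an immune transcription factor, was 3.53-fold higher in line A and 2.51-fold in line B. BIK1, a receptor-like kinase, had log2 ratios of 0.40 and 0.44, and EFR was under the floor throughout. The list's median was 0.40 in line A (random lists -0.37 to 0.19) and 0.44 in line B (-0.36 to 0.25). Of 3 salicylic acid genes, WRKY53, a regulator of senescence and defence, was 2.53-fold higher in line A (177 against 70.0) and had a log2 ratio of 0.01 in line B. SAG101 and GRX480 had log2 ratios of 0.06 and 0.56 in line A and of -0.30 and -0.06 in line B. The list's median was 0.56 in line A (random lists -0.53 to 0.25), -0.06 in line B (-0.51 to 0.36) and 0.62 between the lines (-0.42 to 0.34). A floor of 10 gave -0.42 in line B and 1.21 between the lines. A floor of 50 gave 0.00 in line A and between the lines, with SAG101 and GRX480 under that floor on all arrays.

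Photosynthesis genes, 3 of 24 with a named probe set, and reference genes stayed within the random range in each comparison. LHCB4.1, a light-harvesting protein gene, PSAE1 and RCA, the rubisco activase gene, had log2 ratios of -0.08, 0.16 and -0.19 in line A and 0.12, 0.26 and -0.15 in line B. The list's medians were -0.08 and 0.12, and the line A median was 0.074 under quantile normalization. The flavonoid genes DFR, UF3GT and UGT75C1 were at or under a signal of 25.3 on every array. With DFR and UGT75C1 under the floor throughout, the flavonoid median was 0 by construction and shows nothing about these genes. Of 4 reference genes, none differed 2-fold. Their median log2 ratio was 0.01 in line A (-0.0083 under quantile normalization) and -0.17 in line B, with TUB6, a tubulin gene, at -0.41 in line B. Of the markers for other tissues and cell types, GC1 (AT1G22690), a guard cell gene, had log2 ratios of -0.25 and -0.37, and EXPA7, a root hair expansin, was under the floor on all arrays. Each of the following lists had 1 named gene. PDF1.2, described above, was the ethylene gene. BCAT4, of glucosinolate synthesis, had log2 ratios of 0.43 in line A and -0.39 in line B, and AUR1, a mitotic kinase gene, of -0.35 and -0.18. The clock gene GI had 0.23 and 0.17 with a Col-0 signal under the floor, and the senescence gene WRKY6 had a signal of 34.7 in line A and was under the floor on the other arrays. The heat shock gene HSP17.6C was under the floor on all arrays. No member of the salt, drought and abscisic acid, jasmonate, oxidative stress, flower or seed lists has a probe set named here.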

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

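The tests of scaling, of low signals and of the spread of signals in line A were set up before their results were seen, and those of RNA integrity and of the Col-0 array afterwards.

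Among the control probe sets, which no comparison uses, the one for 25S ribosomal RNA was 2.09-fold above Col-0 in line B. It was 1.55-fold above Col-0 in line A, and its Col-0 signal of 28.9 was near the floor of 25. AT2G18690 stood out because the lines lay on opposite sides of Col-0: its log2 ratio was 0.97 in line A and -0.87 in line B. That difference was not tested, since each line has 1 array.

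The first pattern is that 159 probe sets were higher in both lines and 20 lower, an imbalance whose size depends on dim signals and on the threshold, since a floor of 10 gave 221 higher and 110 lower, and 1.5-fold gave 411 and 264. Scaling differences of the kind that quantile normalization and loess centring remove do not account for the number of higher ones. At least 176 probe sets were higher in both under each of these. Both methods assume an equal bulk signal on the arrays, so they cannot test that assumption. Dim signals do not account for the number either. With the higher signal at 100 or more in both comparisons, 129 were higher and 11 lower, against at most 15 higher in the simulation. RNA degradation common to all transcripts would move every 3′ to 5′ control ratio one way. In both lines 4 of 6 ratios, those of actin and GAPDH, were above Col-0 and the 2 of ubiquitin below it. The pair that moved furthest apart differed by 0.66 on the log2 scale in the line where that gap was smaller. Ratios of the same transcript also disagreed, with log2 changes of 0.44 and 0.02 for actin in line A. The opposite directions argue against a uniform bias, but weakly given that disagreement, and leave one in some transcripts open. A difference of the Col-0 plants or array unrelated to MKK2 remains open beside an effect of both transgenes, since the covariance exceeded the simulated one by 0.029 and both explanations predict such an excess. With 1 Col-0 array these cannot be told apart.

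The second pattern is that the shared change was larger in line A, where 125 of the 159 probe sets had the higher ratio, at a median of 3.48-fold in line A and 2.82-fold in line B. A wider spread of signals on the line A array as a whole would shrink the difference under quantile normalization, but its median went from 0.30 to 0.28 on the log2 scale. Quantile normalization also assumes an equal bulk signal on the arrays, so it cannot test that assumption. The median log2 ratio of the hybridization spike controls over Col-0 was -0.29 in line A and -0.59 in line B. Scaling to these spikes would lower line A against line B by about as much as the median difference of 0.30, and was not run. The larger change in line A thus rests on the assumption of an equal bulk signal. A biological difference between the lines, in the MKK2 variant or in transgene level, was not tested and may be a candidate explanation, as may a difference between the plants of each array.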

How the results depend on the processing

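All settings in this part were chosen before the data were examined. With the 2-fold threshold, the number of probe sets higher in both lines lay between 129 and 221 under every scaling, floor, pseudocount and probe set choice. No list median or named gene outside its random range or threshold changed sign. Values as deposited gave the same counts, but their scale differs from the main one by almost nothing, so that choice shows little. Of 412 alternative values for 59 results on named genes, 390 moved by less than the local spread between the lines and 22 by more, 21 of them with the higher floor or the pseudocount. Of 56 results at 2-fold or more, 7 of 391 alternative values were under 2-fold, among them AT2G40430 and AT5G02830 between the lines. The settings meant for the MKK2 signal were not run, since no probe set is named as MKK2 here. No paired analysis was possible because each group has 1 array. Signals near background limit the counts, which changed with the floor.

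Under quantile normalization 58 probe sets were lower in line A, the cold response median between the lines was 0.26, and the photosynthesis medians were 0.074 in line A and 0.025 between the lines. Under loess centring 52 were lower in line A and 13 in both. With a floor of 10, 508 were lower in line A, 405 higher and 360 lower in line B, 276 higher and 346 lower in line A against line B, and 110 lower in both. The medians were then 0.98 and 0.69 for cold response in lines A and B, -0.42 and 1.21 for salicylic acid in line B and between the lines, 0.95 for touch in line A and -0.18 for flavonoid genes in line A. With a floor of 50, 37 were lower in line A, 57 in line B and 11 in both, and 73 were higher and 13 lower in line A against line B. The medians for cold response in line A and for salicylic acid in line A and between the lines were 0, and those for touch in line A and between the lines 0.013. With the pseudocount of 16, 11 were lower in both, and the medians were 0.55 for cold response in line A, 0.44 for pattern-triggered defence between the lines, and -0.11, 0.087 and -0.092 for flavonoid genes in line A, in line B and between the lines. At 1.5-fold, the numbers higher and lower were 754 and 891 in line A, 701 and 709 in line B, 533 and 550 between the lines, and 411 and 264 in both. At 3-fold they were 121 and 12, 69 and 17, 21 and 1, and 60 and 4. For the variant called w.t.4 over the one called EE4, the titles give 133 higher and 41 lower, and the source names give 41 higher and 133 lower, while lines A and B stay the same arrays. With the mean in place of the median, cold response was 0.59 in line A, pattern-triggered defence 0.74 in line A, 0.59 in line B and 0.15 between the lines, and touch 1.07 in line A and 0.83 in line B. The thresholds, floors and exchanged labels change these values by construction. Why the balance of higher and lower probe sets turned with a threshold or floor was not tested, nor was the cause for the other settings.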

Other observations

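The gene families and plastid genes described here were chosen after seeing the data. Every symbol stem shared by 8 or more named genes was evaluated like the fixed lists, 33 stems in all, together with the plastid genome. The stems are not all separate families: EXP and EXPA hold the same 10 genes, NRT holds all 11 NPF genes, and TON and TRM share 14 of their 15. Of 102 values, 11 lay outside the central 95% of random lists, where chance would give 5.1. Of these, 5 were medians of line A over line B: CML at 0.41 (random lists -0.17 to 0.08), PUB at 0.14 (-0.28 to 0.14), BZIP at 0.12 (-0.09 to 0.03), SWEET at -0.12 (-0.08 to 0.00) and RALFL at 3.5e-05 (-0.01 to 0.00). The RALFL median is practically 0, so lying outside the range can mean very little where many members are under the floor. The PUB median between the lines lay at the edge of its range, at 0.1397 against 0.1396. The other 6 were medians over Col-0, of PUB and XTH in both lines, CML in line A and PRA1 in line B. Of 9 plant U-box ubiquitin ligase genes (PUB), 4 were 2-fold or more higher in line A and 2 in line B. PUB19 was 2.28-fold and 2.24-fold higher, PUB25 2.33-fold and 1.51-fold, PUB26 1.70-fold and 1.88-fold, and PUB22 at least 2.15-fold higher in line A, while PUB24 was 1.27-fold and 1.76-fold lower. The family's median log2 ratio was 0.77 in line A (random lists -0.34 to 0.08) and 0.34 in line B (-0.29 to 0.17). The calmodulin-like family (CML) had 3 of 8 genes 2-fold or more higher in line A and 2 in line B. Its median was 0.16 in line A (-0.24 to 0.04) and, within the random range, 0.01 in line B (-0.22 to 0.12). CML23 was 3.58-fold higher in line A and 2.21-fold in line B, and CML42 had log2 ratios of 0.04 and -0.59. Xyloglucan endotransglucosylases (XTH), which remodel cell walls, had medians of 0.14 in line A (-0.14 to 0.00) and 0.24 in line B (-0.08 to 0.05), and XTH18 was at least 3.28-fold higher in line B. The PRA1 family, linked to vesicle traffic, had a median of -0.42 in line B (-0.26 to 0.16) and, within the random range, of -0.18 in line A (-0.28 to 0.09). PUB23, CML38 and CML37 were already named above, so these families are not independent of the counts. Under quantile normalization and loess centring, all 11 medians outside the range kept their sign except that of RALFL, which was 0 under both, and the CML median in line B was 0 under quantile normalization. Family medians with other floors or the pseudocount are not given here, although other floors moved several medians of the fixed lists. The autophagy genes (ATG) stayed within the random range, at -0.12 in line A and -0.18 in line B.

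Of 69 genes of the plastid genome, 3 were 2-fold or more higher in line A, 2 in line B, and 0 lower in either. Their median was -0.08 in line A and -0.07 in line B, within the random range, and the line B median lay just outside it under loess centring (-0.07, random lists -0.07 to 0.07). The genes at 2-fold or more were rbcL, psbB and, in line A, petG. Of these rbcL, the large subunit of rubisco, was 2.53-fold and 2.09-fold higher, psbB 2.19-fold and 2.52-fold, and petG 2.77-fold and 1.96-fold. The psbA signal was 1.12-fold lower in line A and 1.97-fold lower in line B.

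AT4G29780, which was 6.46-fold and 3.87-fold higher, lies 3 protein-coding genes from MKK2 on the reference chromosome. Of the 6 named genes within 10 on either side of MKK2, it was the only one that differed 2-fold in either line. AT4G29780 had been picked for its ratio first, and a link between its position and the transgene was not tested. AT4G29790, between them, had log2 ratios of -0.74 and -0.65.

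Of 18 probe sets for the hybridization spikes, 17 were below Col-0 in line A and 18 in line B, at a median of 81.6% and 66.4% of the Col-0 signal. With signals under 25 set to 25, the largest ratio between the lines belonged to a probe set whose gene is not named here and which can read more than 1 gene. It was 8.79-fold below Col-0 in line B (54.4 against 478) and had a signal of 523 in line A. On the same scale, the probe set furthest below Col-0 in line A, also not named here, was 6.70-fold lower there and 3.46-fold lower in line B.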
